A study of Mus musculus with 6 samples.

How the data were processed

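The data are 6 libraries of captured nascent RNA (EU-seq) from mouse embryonic stem cells, 3 clones with and without 4OHT for 2 h. Per the labels' protocols, total RNA was isolated with DNase treatment, RNA labelled with ethynyl uridine was purified by click chemistry on beads, and libraries were made with the NEB Next Ultra 2 kit. The submitters' processing notes name STAR, featureCounts and the mm10 build. Their versions and settings, and whether exons or whole gene bodies were counted and whether strand was used, are not given in the sources used here. The deposited values are raw counts, whole-number read counts per gene symbol, with no normalization by the authors. Because strand is not stated, overlapping genes cannot be separated, and this is said beside each named gene whose span overlaps another. How reads shared by near-identical copies or repeats were treated is not given either. A 15 min label reports mainly transcription in that window, but mature RNA carried through the capture would be counted alike.

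The table holds 25,899 gene symbols, of which 6497 had no count in any library, and no row that names no gene. Each column was tied to a sample by its clone letter and time. Symbols were matched to GENCODE M21 (GRCm38, the same assembly as mm10) for positions and lengths: 25,557 were found once, 38 more than once and 304 not at all. The clones are taken as the replicates. Nothing says that clones were cultured on separate days, so p-values measure the spread between these libraries. Within each group, libraries differed by more than counting noise (chi-square per gene 2.29 to 11.3), so none was treated as a copy of another. Counting intervals and floors cover counting error only, since reads carry no molecular identifiers.

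Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, minimum total 15), leaving 13,869, libraries were scaled by TMM, and the treatment was fitted with glmQLFit and glmQLFTest on the 3 against 3 libraries with no clone term. P-values were adjusted by Benjamini-Hochberg and called below 0.05. The SE of a log2 fold change is its size divided by the square root of F. Log2 CPM used a prior count of 2. TMM factors were 1.08, 1.08 and 1.05 untreated and 0.929, 0.932 and 0.939 after 4OHT, so that scaling by library size alone lowers every fold change by about the -0.20 given with the results. Like every scaling within libraries, TMM cannot show a change in total transcription.

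The clone letters pair the libraries, since the labels name the same clone in both groups. Deviations from the group means correlated at 0.282, 0.165 and 0.357 within clones a, b and c, and between -0.283 and 0.068 across letters. The fit with clone as a block was an alternative, and its value is printed beside a result where it changes the call of a named gene or list or moves a count by over 1.5 times. Clone differences were tested with a joint test of the clone terms beside treatment.

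The study's comparison and all gene lists, rules and alternatives, save those named below as added, were fixed before the data were examined. The 27 lists cover ERK immediate early genes, ERK pathway negative feedback, the ETS and FGF pathway, naive pluripotency, general pluripotency, formative and primed epiblast, primitive endoderm, trophoblast, primitive streak and mesendoderm, neural ectoderm, WNT, LIF and STAT3, NODAL and BMP, SRF and YAP and oestrogen receptor targets, ribosome biogenesis, AP-1 and invasion genes, glycolysis, cholesterol synthesis, p53 targets, heat shock and unfolded protein response, cell cycle, 2-cell-like state, fibroblast and feeder cells, ribosomal proteins, mitochondrial transcripts and nuclear non-coding RNA. They hold 500 genes, 36 of them in more than 1 list. Lists with at least 5 tested members were tested on log2 CPM with camera (limma 3.58.1, inter-gene correlation 0.01), which compares a list with all other genes, and 24 qualified.

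Named genes are the 12 with the largest rise and the 12 with the largest fall among called genes with a mean log2 CPM of at least 2 and the same direction in 3 clones, passing over symbols without a descriptive name. The rule would also pass over genes with unresolved copies, but Lefty1, a near copy of Lefty2, was kept among the 12 falls. They are joined by up to 4 members per list with the smallest adjusted p, and by Esr1, Egr1, Fos, Dusp6, Spry4, Etv4, Myc, Nanog, Klf4, Esrrb, Tbx3, Sox2, Pou5f1, Gata6, Fgf5, Gapdh and Actb whatever their values. Some genes that this rule allows are not reported here. List members outside this rule are named where a count of members that rose, fell or did not pass the test calls for it. The alternatives were DESeq2 size factors, library size, no filter, a filter of CPM of at least 1, DESeq2 1.42.0, limma-voom, the clone block in edgeR and DESeq2, an adjusted p of 0.01, a log2 fold change of at least 1, each library and each clone left out, and for lists an estimated correlation, fry, the block and library size. Scaling to 13 high-count loci, leaving them out and leaving out chromosome 8 were added after seeing the data. Gene families in the closing section were also chosen after seeing the data. Those loci each took over 0.3% of counts in every library.

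The fits were tested on counts simulated from the real means and library sizes, with 200 changed genes among 13,869. For the treatment, 4% of genes changed 1.25-fold were called, 58% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, with 0.0594% of unchanged genes called. For clones, 90% of 2-fold changes in clone c and 0.134% of unchanged genes were called. Of the lists, the raised one was called and 0 of 20 unchanged ones. Each gene was simulated independently of the others, so this does not test camera on lists with correlated members. In the data 57.1% of tested genes were called, against 200 of 13,869 changed here. An adjusted p depends on how many genes change, so the shares called here do not carry over to the data.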

Results

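Newly made RNA was measured in mouse embryonic stem cells of the E14tg2a line (129SV background) that stably carry a cassette for a kinase fusion that responds to 4-hydroxytamoxifen (4OHT). Adding 4OHT switches on the ERK signalling pathway through this fusion. Cells were grown in serum medium with LIF and 2 µM CHIR99021, an inhibitor of GSK3 that activates WNT signalling. For the last 24 h before treatment the medium held serum, LIF and 250 nM PD173074, an inhibitor of FGF receptors, and cells were then left untreated or given 250 nM 4OHT for 2 h. Ethynyl uridine, which is built into RNA as it is made, was present at 5 mM for the 15 min before RNA isolation, and the labelled RNA was captured and sequenced. There were 6 libraries, 1 untreated and 1 treated library from each of 3 clones named a, b and c. Total counts were 11,549,152, 12,168,380 and 9,745,747 in untreated clones a, b and c, and 9,431,819, 8,686,555 and 7,295,334 after 4OHT. A count of 3 in a library stood for 0.247 to 0.411 CPM (counts scaled to library depth), the upper limit that a count of 0 allows. CPM below are TMM-normalised, and errors are SE for log2 fold changes and SD for CPM, with n = 3 libraries per group.

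The design asks which genes are transcribed more or less within 2 h of switching on ERK. It holds no 4OHT-treated cells without the cassette, and no library is labelled as a solvent control. Effects of 4OHT itself or of handling therefore cannot be told apart from those of ERK. Several immediate early genes were among the largest rises. The zinc-finger transcription factor Egr1 (chromosome 18, 34,859,823 to 34,864,984, GRCm38) rose from 66.2 ± 17.3 to 3834 ± 152 CPM, a log2 fold change of 5.86 ± 0.18. The cytoskeleton-associated immediate early gene Arc rose from 13.4 ± 3.04 to 1026 ± 249 CPM (6.27 ± 0.21), and Cavin1, a coat protein of caveolae, from 4.86 ± 2.59 to 316 ± 33.3 CPM (6.07 ± 0.23). Among falls, Fgf10, a fibroblast growth factor, went from 24.5 ± 1.52 to 2.55 ± 0.312 CPM (-3.25 ± 0.15), and Plpp3, a lipid phosphatase, from 177 ± 13.6 to 23.5 ± 4.10 CPM (-2.90 ± 0.11).

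The 12 largest rises also held Egr3, Lor, Iqsec3, Rrad, Sec14l3, Gpr142, Phlda1, Cyth4 and Dusp2. Egr3 (9.12 ± 0.28), Iqsec3 (8.08 ± 0.25), the small GTPase Rrad (7.65 ± 0.40), Sec14l3 (6.82 ± 0.47) and Gpr142 (6.26 ± 0.28) had at most 12 counts each over the 3 untreated libraries, so the exact size of those rises is loosely set. Lor, which encodes the skin protein loricrin, had 3 counts over the untreated libraries against 1219 after 4OHT, a depth-scaled ratio of 615 with a 95% counting interval of 210 to 2987. Phlda1 rose by 5.72 ± 0.32, Cyth4 by 5.52 ± 0.35 and Dusp2, a phosphatase that acts on ERK, by 5.49 ± 0.52, the last 2 on 15 and 9 untreated counts and so as loosely set. The other large falls were in Trim67 (-3.84 ± 0.27), Sh2d4a (-3.81 ± 0.31), the homeobox gene Hoxc13 (-3.69 ± 0.29), Slc5a11 (-3.55 ± 0.18), the arginine methyltransferase Prmt8 (-3.21 ± 0.17), Rab3il1 (-3.18 ± 0.35), Sfrp4 (-2.94 ± 0.30), Gnat3 (-2.93 ± 0.28) and Capn5 (-2.91 ± 0.12), whose span overlaps Omp. Lefty1, an inhibitor of NODAL signalling, fell by 3.18 ± 0.26 on the log2 scale, and its close relative Lefty2, which may share reads with it, changed by -2.57.

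Of 13,869 genes tested, 3953 were higher and 3968 lower after 4OHT, 57.1% in all (edgeR quasi-likelihood test, adjusted p below 0.05). Large changes were fewer: 947 genes were higher and 1324 lower with at least a doubling or halving, 108 rose by 3 or more on the log2 scale and 25 fell by as much. The direction was shared by all 3 clones for 3945 of the higher and 3960 of the lower genes, counts largely set by calling the genes on these same libraries. Across all tested genes, the response of single clones gave Pearson's r of 0.910 for a and b, 0.886 for a and c, and 0.884 for b and c, a correlation across genes, which are not independent replicates. The balance of rises and falls depended on the scaling: by library size alone 2407 genes were higher and 5684 lower (29.7% of calls higher, against 49.9%), and all fold changes shifted by a median of -0.20.

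**Figure D1:**
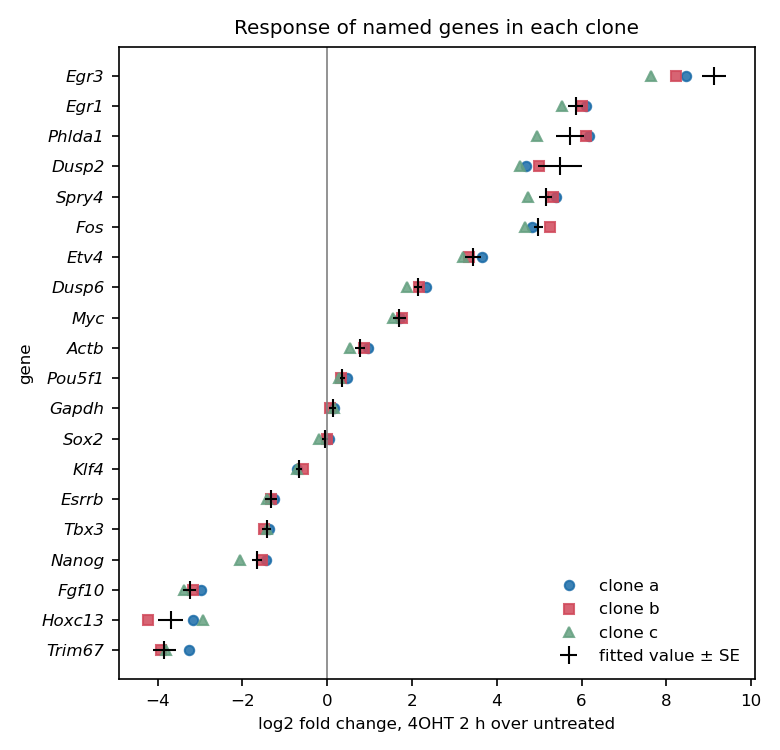
Log2 fold change (4OHT 2 h over untreated, horizontal axis) of 20 named genes, with 1 symbol per clone computed from log2 CPM with a prior count and the fitted value with its SE as a black cross. Egr3, Egr1 and Phlda1 lie highest and Trim67, Hoxc13 and Fgf10 lowest, and the 3 clones lie on the same side of 0 for each gene shown except Sox2.

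The genes fixed beforehand as ERK immediate early genes rose almost as a whole. Of 27 tested, 24 were higher and 2 lower, with a median log2 fold change of 2.03. Fos, the AP-1 subunit, rose from 4.20 ± 0.632 to 132 ± 8.65 CPM (4.98 ± 0.11), Egr2 by 5.14 ± 0.15, and the growth regulator Myc from 9.15 ± 1.62 to 29.7 ± 4.08 CPM (1.70 ± 0.15). The 2 that fell were Nr4a2 (-0.78) and Gdf15 (-0.72), and Btg2 did not pass the test (0.07). The list was higher by camera (adjusted p = 5.7e-10), and adjusted p = 0.54 with an estimated correlation.

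Genes that restrain the ERK pathway rose too: 13 of 18 were higher and 2 lower, with a median of 2.00. Spry4, a receptor tyrosine kinase inhibitor, rose from 39.6 ± 6.30 to 1407 ± 214 CPM (5.16 ± 0.15). The ERK phosphatases Dusp6 and Dusp5 rose by 2.14 ± 0.09 and 3.80 ± 0.19, and Spred1, an inhibitor of RAS signalling, by 1.87 ± 0.08. Lrig3 (-1.77) and Lrig1 (-0.91), which dampen growth factor receptors, fell, while Spry1 (-0.07), Spred2 (0.16) and Rasa1 (-0.13) did not pass the test, although Spred2 did with clone as a block (edgeR adjusted p = 0.0028, against 0.18 without it). The list was higher by camera (adjusted p = 0.00039), with adjusted p = 0.54 with an estimated correlation.

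Of 14 tested ETS and FGF pathway genes, 9 were higher and 2 lower (median 0.66), against 8 and 3 by library size (median 0.46) and 6 and 3 scaled to the high-count loci (median 0.36). The ETS factors Etv4 and Etv1 rose by 3.44 ± 0.18 and 2.27 ± 0.16 and Elk4, which overlaps Mfsd4a, by 0.99 ± 0.08. Fgf4, the main FGF ligand made by embryonic stem cells, fell from 267 ± 24.1 to 48.1 ± 5.64 CPM (-2.47 ± 0.10). Fgf5, a marker of the primed epiblast, was too low to test, with 10 counts over the untreated and 7 over the treated libraries. The list was higher by camera (adjusted p = 0.039), with adjusted p = 0.54 with an estimated correlation. It did not pass with clone as a block (adjusted p = 0.052), without the treated library of clone c (0.060) or without the untreated library of clone a. Fgfr2, a member that rose by 0.34, is 1 of 13 loci with the highest counts, whose log2 fold changes were 0.20 to 0.38.

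Genes of the naive pluripotent state fell more often than they rose: 12 of 26 were lower and 5 higher (median -0.40, or -0.60 with 20 lower by library size). The transcription factor Nanog (chromosome 6, 122,707,489 to 122,714,633) fell from 317 ± 18.1 to 100.1 ± 18.98 CPM (-1.66 ± 0.12). Esrrb (-1.32 ± 0.14), Tbx3 (-1.42 ± 0.11), Prdm1 (-1.72 ± 0.07) and Klf4 (-0.66 ± 0.07) fell too. Klf5, another Krüppel-like factor, rose by 1.21 ± 0.07, and Manba (1.37), Dazl (1.19), Zfp42 (0.67) and Zfp57 (0.56) were higher as well. Sox2 did not differ in this test (-0.04 ± 0.07, edgeR adjusted p = 0.63), although scaling by library size gave -0.24 with an adjusted p of 0.014 (range over all alternatives 0.014 to 0.95). The list was lower by camera (adjusted p = 0.036, and adjusted p = 0.60 with an estimated correlation), a call also lost without the treated library of clone c (adjusted p = 0.060) and by library size (0.085).

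Broader pluripotency genes went both ways, with 5 of 15 higher and 6 lower, or 3 and 8 by library size with a median of -0.25 against -0.06 (camera adjusted p = 0.70). The zinc-finger factor Sall4 fell from 355 ± 16.6 to 160 ± 8.24 CPM (-1.15 ± 0.07) and Tdgf1, a NODAL co-receptor, by 1.33 ± 0.08 on the log2 scale, while Dppa2 (0.97 ± 0.09) and Dppa4 (0.86 ± 0.07) rose. Pou5f1 (OCT4) went from 175 ± 1.10 to 225 ± 13.6 CPM (0.36 ± 0.06), and was not called by library size (0.16) or when scaled to the 13 high-count loci (0.05). Among 18 formative and primed epiblast genes, 10 were higher and 4 lower (median 0.61), against 9 and 4 by library size (median 0.41) and 8 and 5 scaled to the high-count loci (median 0.30). The list did not pass the test (camera adjusted p = 0.061, or 0.0086 by library size, and adjusted p = 0.54 with an estimated correlation). Pou3f1 (OCT6) rose from 2.07 ± 0.266 to 12.1 ± 1.11 CPM (2.52 ± 0.17), the DNA methyltransferase Dnmt3a by 1.94 ± 0.09 and Sox4 by 1.17 ± 0.08.

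Lineage markers showed no shared direction. In the primitive endoderm list 7 of 22 were higher and 7 lower, and the median of 0.12 turned to -0.07 by library size (camera adjusted p = 0.77). Sparc rose from 59.9 ± 8.85 to 356 ± 31.1 CPM (2.58 ± 0.11), Grb10 by 1.39 ± 0.10 and the laminin chain Lamb1 by 0.92 ± 0.06, whereas Dab2 fell by 1.92 ± 0.14 on the log2 scale. Gata6, the early endoderm factor, had 2.67 ± 0.529 CPM untreated and 1.76 ± 0.259 after 4OHT (-0.60 ± 0.26, edgeR adjusted p = 0.072), and passed the test by library size (-0.80, adjusted p = 0.023, range over alternatives 0.012 to 0.42). Of 14 trophoblast genes 4 were higher, among them the keratins Krt8 (1.89 ± 0.26) and Krt18 (1.81 ± 0.26) and the factor Tead4 (1.31 ± 0.12), and 3 lower, among them Id2 (-2.47 ± 0.19), with a median of 0.11, or -0.08 by library size (camera adjusted p = 0.64). Most primitive streak and neural genes were too low to test: of 7 streak genes 3 were higher and 2 lower (adjusted p = 0.36), and of 5 neural genes 1 was higher and 3 lower (adjusted p = 0.47). Fgf8 (2.25 ± 0.40) and Evx1 (2.38 ± 0.60) were higher at under 2 CPM, the neural intermediate filament gene Nes rose by 1.02 ± 0.14, and Map2 fell by 0.60 ± 0.10 on the log2 scale.

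Targets of other signalling pathways also split. Of 10 WNT targets 3 were higher and 4 lower (camera adjusted p = 0.78): Tcf7 rose by 1.58 ± 0.08 and Lef1, which overlaps Gm42449, by 1.59 ± 0.19, while Ccnd1 (-1.36 ± 0.21) and Fzd7 (-0.70 ± 0.08) fell. Of 14 LIF and STAT3 targets 4 were higher and 7 lower (adjusted p = 0.33), with falls in Icam1 (-1.77 ± 0.10), Bcl3 (-1.55 ± 0.14) and the kinase Pim3 (-1.22 ± 0.10). Among 17 NODAL and BMP targets 5 were higher and 8 lower (adjusted p = 0.59). Skil, a repressor of SMAD signalling, rose by 1.39 ± 0.07, and Lefty1 was among the genes that fell. As 4OHT binds oestrogen receptors, their targets were followed as well: 2 of 12 were higher, among them Esr1 itself, and 5 lower (adjusted p = 0.47), with Cxcl12 (-2.97 ± 0.29) and Myb (-1.44 ± 0.12) lower.

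Reads at Esr1, the oestrogen receptor alpha gene, bear on the cassette, whose transcripts cannot be told apart here from those of the mouse gene. Esr1 rose from 35.9 ± 2.28 to 109 ± 2.74 CPM, and was higher in 3 of 3 clones.

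In the AP-1 and invasion list 10 of 15 were higher and 1 lower (median 0.52, or 0.32 with 8 higher by library size and 0.21 with 7 scaled to the high-count loci). The urokinase receptor gene Plaur rose from 26.7 ± 2.82 to 515 ± 104 CPM (4.27 ± 0.15), the EGF family ligand Hbegf by 3.58 ± 0.11 and Ptgs2 by 3.96 ± 0.24. Lif fell (-1.50). Cd44, which rose by 0.31, belongs to the 13 high-count loci. That list was higher by camera at adjusted p = 0.024 (adjusted p = 0.54 with an estimated correlation, and 0.060 without the treated library of clone c). Of 17 SRF and YAP targets 11 were higher and 2 lower (median 0.58, or 0.38 with 8 higher and 3 lower by library size and 0.29 with 6 and 3 scaled to the high-count loci). Actb rose from 591 ± 118 to 1006 ± 46.8 CPM (0.77 ± 0.12), Actg1 by 1.05 ± 0.07 and Fhl2 by 1.68 ± 0.15. Amotl2 (-1.03 ± 0.07) and Tpm1 (-0.69 ± 0.08) fell. It passed camera narrowly (adjusted p = 0.049, and adjusted p = 0.59 with an estimated correlation), and leaving out the untreated library of clone a or b or the treated library of clone c ended the call (highest adjusted p = 0.078). Of 8 tested fibroblast and feeder markers 3 were higher and 2 lower (adjusted p = 0.33): Twist1 rose from 0.499 ± 0.321 to 18.1 ± 2.02 CPM (5.21 ± 0.29), Vim by 2.96 ± 0.24 and Col1a1 by 3.45 ± 0.45, while Pdgfrb (-0.91) and Col5a2, which overlaps Gm38211 (-1.44 ± 0.36), fell.

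Of 20 cholesterol synthesis genes 16 were higher and 1, Mvk (-0.42), lower (median 0.39), against 9 higher by library size (median 0.19) or scaled to the high-count loci (median 0.09). Hmgcs1 rose by 1.29 ± 0.09, Sc5d by 1.00 ± 0.10 and the regulator Srebf2 by 0.90 ± 0.06 (camera adjusted p = 0.00061, and adjusted p = 0.54 with an estimated correlation). Of 20 glycolysis genes 13 were higher and 1 lower (15 and 2 with clone as a block, median 0.47), against 11 and 2 by library size (median 0.27) and 6 and 2 scaled to the high-count loci (median 0.16). Phosphofructokinase Pfkp, which overlaps Pitrm1, rose by 2.04 ± 0.18, Gpi1 by 1.10 ± 0.08 and Pdk1 by 1.00 ± 0.10, while the hexokinase Hk1 fell by 1.79 ± 0.14 on the log2 scale (camera adjusted p = 0.0062, and adjusted p = 0.54 with an estimated correlation). Of 24 cell cycle genes 15 were higher and 2 lower (median 0.31), but 6 and 5 by library size (median 0.11) and 2 and 2 scaled to the high-count loci (median 0.01). Pcna rose by 0.73 ± 0.08 and Ccnb1 by 0.58 ± 0.06, while Ccnd1 and Ccnd3 (-0.47) fell (camera adjusted p = 0.036, and adjusted p = 0.54 with an estimated correlation). Ribosome biogenesis genes were higher in 10 of 26 (16 with clone as a block) and lower in 1 (median 0.17), with Heatr1, which overlaps Lgals8, rising by 0.64 ± 0.06 and Wdr43 by 0.44 ± 0.06, but the median turned to -0.02 by library size and -0.13 when scaled to the high-count loci (camera adjusted p = 0.036, and adjusted p = 0.54 with an estimated correlation). The cell cycle and ribosome biogenesis calls were lost by library size (adjusted p = 0.078 and 0.26) and without the treated library of clone c (0.057 and 0.065), and the latter also without the untreated library of clone a or b.

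Stress genes moved in both directions. Of 19 heat shock and unfolded protein response genes 11 were higher and 3 lower (median 0.34), but 7 and 4 by library size (median 0.14) and 4 and 3 scaled to the high-count loci (median 0.04). The stress factor Ddit3 (CHOP) rose from 13.6 ± 2.66 to 72.3 ± 7.18 CPM (2.40 ± 0.13), Hspa8 by 0.80 ± 0.08, Atf4 by 0.68 ± 0.06 and Hsph1 by 0.62 ± 0.06. That list passed camera narrowly (adjusted p = 0.049, and adjusted p = 0.54 with an estimated correlation), and not without the untreated library of clone b (0.067) or the treated library of clone a. Of 16 p53 targets 10 were lower and 2 higher, or 4 higher with clone as a block (median -0.41, camera adjusted p = 0.097). Trp53inp1 fell by 1.18 ± 0.09, Ccng1 by 0.88 ± 0.08 and Eda2r by 0.63 ± 0.07 on the log2 scale, whereas Pmaip1 (1.30) and Mdm2 (0.34) rose.

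Gapdh and the ribosomal protein genes moved little in the main fit, unlike Actb, which rose as given above. Gapdh, which overlaps Iffo1, had 488 ± 37.2 CPM untreated and 533 ± 52.97 after 4OHT (0.13 ± 0.09, edgeR adjusted p = 0.23), and was called with clone as a block (adjusted p = 0.012, range over alternatives 0.012 to 0.61). Of 30 ribosomal protein genes 3 were higher and none lower, or 14 and 1 with clone as a block (median 0.08, camera adjusted p = 0.26), but by library size none was higher, 9 were lower and the median turned to -0.11. Rps6 (0.28 ± 0.06), Rpl27 (0.25 ± 0.07) and Rpl32 (0.17 ± 0.06, overlapping Cand2) made up the 3, and the call of Rpl32 was lost without any 1 of 5 libraries (highest edgeR adjusted p 0.15, without the untreated library of clone b). Rpl8 was called only in fits with the clone block (edgeR adjusted p = 0.00095, against 0.071 without it) or without the untreated library, or both libraries, of clone c (range over alternatives 0.00095 to 0.86). All 13 mitochondrial genes in the table had 0 counts, no gene of the nuclear non-coding RNA list was in the table, and of the 2-cell-like list 1 gene, Arg2, was tested (0.63 ± 0.21). Arg2, which overlaps Vti1b, was higher, but not by DESeq2, by library size or without the untreated library of clone a or b (edgeR adjusted p = 0.091 and 0.066) or the treated library of clone a (0.084).

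In all, 10 of the 24 lists with at least 5 tested members were higher and 1 lower by camera with a preset correlation, and none was called with an estimated correlation (adjusted p 0.54 to 0.83). For the LIF and STAT3 list, with an estimated correlation of -0.0025, the camera adjusted p still rose from 0.33 to 0.54. The losses in that setting therefore do not show that correlated members undo the call of each list. Without the treated library of clone c, 5 lists remained higher and none lower: the immediate early, feedback, glycolysis, cholesterol, and heat shock and unfolded protein response lists. Adjusted over the list alone, the counts of members higher and lower stayed as given except in the NODAL and BMP (7 higher, 9 lower), p53 (3 higher, 10 lower) and ribosomal protein lists (1 higher, 0 lower).

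**Figure D2:**
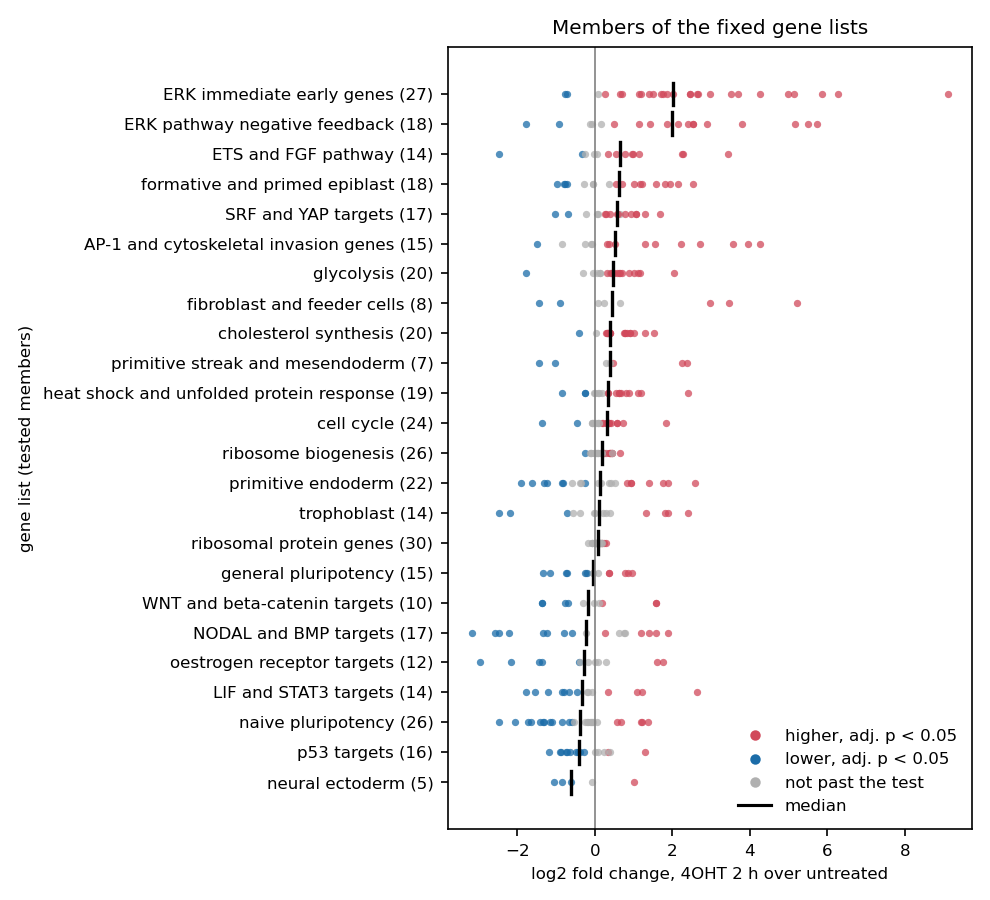
Log2 fold change (4OHT 2 h over untreated, horizontal axis) of each tested member of the fixed lists, with 1 row per list and the number tested in brackets. Red and blue points passed the edgeR test upwards and downwards, grey points did not, and black bars are medians, which reach 2.03 and 2.00 in the immediate early and feedback lists.

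The clones also differed from one another, whatever the treatment. Clone c stood apart: the Y-linked RNA helicase gene Ddx3y had 16.8 CPM in untreated clone c against 83.7 and 85.2 in clones a and b, and 23.7 against 122 and 125 after 4OHT (c against a, -2.34 ± 0.08 in log2). Other Y-linked genes differed less: between c and a, Uty was lower (-0.33 ± 0.06), and Eif2s3y did not pass the test (-0.21 ± 0.07). Gm10800 and Gm10801, neighbours on chromosome 2 that may share reads with repeats, were higher in clone c by 1.32 ± 0.09 and 1.79 ± 0.16. These 5 genes were chosen after their values were seen.

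In a fit with clone and treatment, 1741 genes differed among the 3 clones (edgeR, adjusted p below 0.05), and 3590 at an unadjusted p under 0.05. The separation was mostly that of clone c, with 1891 genes called between c and a, 1330 between c and b and 68 between b and a. At least a 2-fold difference was found for 80, 49 and 1 of these. Of the 1741 genes, 1027 were also changed by 4OHT. Among all 13,869 tested genes 7921 (57.1%) were changed, so a large overlap is no sign of a link. For the differences among clones, DESeq2's likelihood-ratio test called 598 genes. The median response of the genes that rose was 0.55, 0.55 and 0.52 in clones a, b and c, each from 1 library per condition and so without a replicate.

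By position, differences were most frequent on chromosome 8, where 397 of 694 tested genes (57.2%) differed among clones, against 1344 genes elsewhere (10.2%). The median difference between clones c and a over chromosome 8 was 0.40 in the untreated and 0.38 in the treated libraries, against -0.03 to 0.02 and -0.09 to 0.00 over each other autosome. Clone b lay between, 0.16 and 0.14 above clone a. Leaving out chromosome 8, a choice made after seeing the data, 1139 genes differed among clones.

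**Figure D3:**
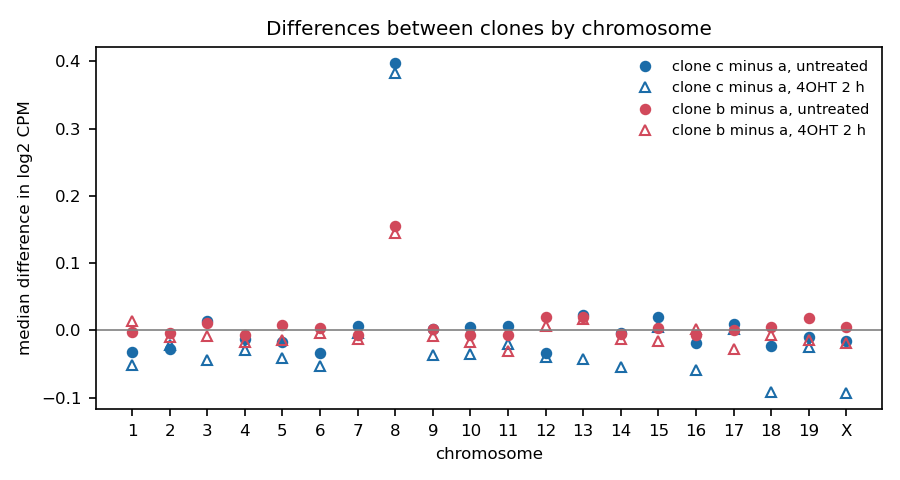
Median difference in log2 CPM between clones (vertical axis) over the tested genes of each autosome and the X chromosome (horizontal axis), for clone c minus a (blue) and clone b minus a (red), in untreated (filled circles) and 4OHT libraries (open triangles). Chromosome 8 lies at 0.40 and 0.38 for c minus a and 0.16 and 0.14 for b minus a, and the others shown lie between -0.09 and 0.02.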

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

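Of 2317 values of 122 named genes under 19 alternatives, 2255 kept their side of the threshold, and 50 kept the direction but not the call. Another 8 were newly called, 4 turned with a call in the main or the alternative fit, and 99 genes kept their call throughout. Values called in neither fit are counted among the 2255 even where they turned, as for Gapdh (lowest -0.18), Rpl8 (lowest -0.12) and Sox2 (highest 0.02). The 4 turned values with a call were Rpl32 by library size (-0.0266) and, scaled to the high-count loci, Rpl32 (-0.136), Rps6 (-0.0276) and Rpl27 (-0.0599), where all fold changes shift by a median of -0.31 by construction. Counts of called genes stayed within 1.5 times the main ones except as follows. By library size 2407 genes were higher. At an absolute log2 fold change of at least 1, 947 were higher and 1324 lower. Scaled to the high-count loci, an alternative chosen after seeing the data, 1379 were higher and 5546 lower (19.9% of calls higher). Leaving out 1 library or 1 clone gave 2713 to 4159 genes higher and 2708 to 4328 lower. With clone as a block, 4725 genes were higher and 4623 lower, keeping 3952 and 3967 of the main calls. Besides those of Gapdh, Rpl8, Spred2 and the ETS and FGF list, the block in edgeR changed the call of no named gene or list save Ddx3y, Gm10800 and the high-count loci Cdk8, Lars2 and Zc3h7a, which it newly called. The block with DESeq2 ended those of Tbx6, Wnt3a, Arg2 and Col5a2, and the causes were not tested.

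With an estimated correlation 0 lists were higher and 0 lower, and the cause was not tested. The camera p is adjusted over all 24 lists, and it rose also where the estimated correlation lay below the preset 0.01. For the formative and primed epiblast list that correlation was 0.00044, and the adjusted p went from 0.061 to 0.54. The loss of calls therefore does not show that correlated members undo the call of each list. With the block, 16 naive pluripotency genes were lower, 9 primitive endoderm genes higher, and 7 NODAL and BMP targets higher and 9 lower. Fry, which does not compare a list with other genes, called 13 higher and 4 lower. By library size 0 were lower. Leaving out 1 library gave 5 to 11 lists higher and 0 to 1 lower. For clone differences DESeq2's likelihood-ratio test called 598 genes (the cause was not tested), leaving out chromosome 8 gave 1139, fewer than the 1344 called elsewhere in the fit with all genes (the cause of that further loss was not tested), and leaving out 1 library gave 1268 to 2524. The smallest changes tried in simulated counts were rarely called, but far fewer genes changed there than in the data, so that share does not carry over.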

Other observations

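The genes in this paragraph were chosen after their values were seen. Both corepressors that bind EGR proteins rose: Nab1 went from 8.81 ± 1.56 to 309.9 ± 13.05 CPM (5.15 ± 0.11 in log2) and Nab2, which overlaps Stat6, from 7.54 ± 1.66 to 332 ± 31.2 CPM (5.48 ± 0.13). Among Janus kinases, Jak1 rose from 50.3 ± 2.25 to 419 ± 56.9 CPM (3.06 ± 0.10) and Jak2 by 2.36 ± 0.08, while Jak3 fell (-1.08). Of the STAT genes, Stat6, whose end overlaps that of Nab2 so that reads of one can be counted at the other, rose by 2.25 ± 0.13, and Stat2 (-1.47) fell. Of 11 JAK and STAT genes 4 were higher and 4 lower, with no shared direction (camera adjusted p = 0.93).

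The genes and families in this paragraph were chosen after the values were seen, so their p-values do not stand as those of fixed lists. Genes that act in adding or removing DNA methylation also parted. Dnmt3a (1.94), Tet3 (0.89) and Dnmt1 (0.49) rose, while Tet1 went from 949.5 ± 82.8 to 264 ± 62.4 CPM (-1.85 ± 0.15), and Dnmt3b (-0.97) and Dnmt3l (-0.52) fell. Of 37 proteasome subunit genes 26 were higher and 2, Psma7 (-0.33) and Psma8 (-0.46), lower, with a median of 0.34, or 0.14 by library size and 0.03 when scaled to the high-count loci (camera adjusted p = 0.00016, and adjusted p = 0.10 with an estimated correlation). Of 29 Mediator subunit genes 13 were higher and 1 lower (5 lower with clone as a block), with Med24 the largest at 2.04 ± 0.15 (camera adjusted p = 0.15), and the list's median turned from 0.19 to -0.01 by library size and -0.12 when scaled to the high-count loci. Of 35 complex I subunit genes 3 were higher and 5 lower, or 6 and 9 with clone as a block, and of 58 replication-dependent histone genes 2 and 1, or 10 and 4 with the block (camera adjusted p = 0.93 for both families). Spearman's rho across 13,744 genes, which are not independent replicates, between span and log2 fold change was -0.03 in the fit with and without the clone block. In spans up to 10 kb, 10 to 50, 50 to 100, 100 to 200 and over 200 kb, 24.7%, 29.7%, 29.8%, 31.7% and 25.2% of genes were higher and 19.5%, 30.0%, 34.4%, 32.5% and 30.3% lower, differences that were not tested.

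The 3 patterns below were noticed in the data and tested on the same data, and of these tests those on the spread of the 13 high-count loci and on the first 20 Mb of chromosome 8 were chosen after the result was seen. Along chromosome 8, genes differed among clones by similar amounts before and after 4OHT, with c above a by 0.35 to 0.47 in each untreated 10 Mb bin beyond 20 Mb that held at least 20 genes. A bias with expression level, gene length or GC content is argued against, since matched genes of other autosomes gave a median of -0.0148 (95% range -0.03 to 0.00). The comparisons made first left a gain of the whole chromosome in some cells of clone c open (10 of 12 untreated bins positive). With clone a as the baseline, the 79 genes of the first 20 Mb go against it, with a median for c minus a of -0.0359 (95% interval -0.08 to 0.02). With clone b as the baseline they do not: c lay above b by 0.21 there and 0.25 beyond untreated, and by 0.19 and 0.24 treated. The 95% intervals of beyond minus first included 0 (-0.01 to 0.07 untreated, -0.07 to 0.09 treated). The step near 20 Mb was thus seen only against clone a, and such a gain in clone c stays open. A gain restricted to the part beyond 20 Mb in clones b and c met the comparison first made for it, whose boundary came from bins already seen: b minus a was higher beyond 20 Mb than before it by 0.42 untreated (0.39 to 0.46) and 0.40 treated (0.35 to 0.44), with 10 of 10 bins positive. As the whole reason it is argued against by that first part itself, where b lay below a (-0.25 untreated, -0.24 treated with a 95% interval of -0.27 to -0.19) although such a gain would leave the clones alike there. Copy-number differences of another layout, with a step near 20 Mb, remain a hypothesis that may account for both parts, and were not tested on DNA here.

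The 13 loci with the highest counts (among them Cdk8, Lars2, Jarid2, Zc3h7a, Taco1, Fgfr2 and Cd44) took 15.5% to 19.97% of each library's counts, and their log2 fold changes lay between 0.20 and 0.38. Their spread around a shared course over the 6 libraries was 0.0612 in log2, against a median of 0.23 in 10000 random sets of 13 among the next 500 genes. Counting depth as the reason stays open: the tightest of 10000 sets among the next 50 genes reached 0.10, but those genes have fewer counts and include genes changed by 4OHT. One shared source of reads, such as a repeated sequence counted at all 13, stays open, because the small spread restates that the loci moved together and adds no support. Whether ribosomal RNA was counted there cannot be told apart either: annotated transcripts of 0 of the 13 loci held a 25-base word of the annotated ribosomal RNA unit, and introns were not searched.

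Genes next to strongly raised genes had higher log2 fold changes than genes next to unchanged ones. The raised genes were 194 called genes with at least a 4-fold rise and a mean log2 CPM of at least 2. The nearest genes within 50 kb upstream of them had a median log2 fold change of 0.27 (of 102, 48 were higher and 26 lower). That median exceeded that of genes upstream of unchanged genes by 0.28 (permutation p = 1e-05, the smallest 100000 permutations can give, and 3e-05 adjusted over 3 comparisons). Downstream genes had a median of 0.16 (of 111, 43 were higher and 19 lower). By library size the medians were 0.07 upstream (32 higher and 32 lower) and -0.05 downstream (36 and 32). Next to unchanged genes they were -0.21 upstream (137 higher and 398 lower) and -0.20 downstream (151 and 420). Genes downstream of raised genes exceeded those downstream of unchanged genes by 0.16 (95% interval 0.05 to 0.35, permutation p = 0.0093, adjusted 0.014). Genes that overlap a raised gene, and neighbours that were themselves among the 194 raised genes, were left out. Genes raised as much at a lower mean CPM, such as Lgi3 upstream of Bmp1 (5.35), were not left out by that rule. For the neighbours kept, reads running past the 3' end as the whole reason are argued against, since downstream minus upstream was -0.12 (95% interval -0.29 to 0.16, permutation p = 0.33, adjusted 0.33). A neighbourhood shared on both sides of raised genes may therefore be involved. Upstream genes on the opposite strand, which includes those with divergent promoters, had a median of 0.56 (19 of 38 higher) against 0.19 on the same strand (29 of 64), a difference that was not tested.

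With 3 libraries against 3 there are only 10 splits, so a share under 0.05 cannot be reached: the real split called 7921 genes (1 of 10 splits called as many) and the highest of the others called 0. Each other split puts treated and untreated libraries in the same group, so the treatment adds to the spread within groups. Counts of genes or lists in those splits therefore do not show what arises without a treatment effect. For gene lists, 2 of 10 splits gave 11 called lists, the real one and that of untreated a, untreated b and treated b against the rest, which parts 1 clone of 3. The splits that part all 3 clones as the real one does called at most 6 lists. Groups of 3 libraries are too small for a test of single outlying libraries, and none was made.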
